A study of Mus musculus with 4 samples.

How the data were processed

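Argonaute PAR-CLIP libraries were made from the cytoplasmic and nuclear fractions of mouse embryonic stem cells (ESCs) and of C2C12 myotubes, per the labels' protocols. In PAR-CLIP, a photoactivatable nucleoside in cellular RNA crosslinks to the bound protein under ultraviolet light and is read as a T-to-C conversion in the sequenced cDNA. Crosslinking was at 312 nm for 5 min. The lysates were digested with RNase T1, which cuts after G, then with RNase T1 again after the immunoprecipitation. In ESCs, expression of HA-FLAG-tagged AGO2 was switched on by doxycycline (2.5 ug/ml) over 15 h, and the protein was captured with a FLAG antibody. In myotubes, fused for 2 days, endogenous Argonaute was captured with a peptide that binds all family members. The labels list 4 samples in 4 groups, with 1 sample per group. Every sample title ends in "(2)", and the labels do not say whether this is a replicate number or a number of pooled samples, so each was taken as 1 library. Cluster tables of 2 samples were used, the ESC cytoplasm and the myotube cytoplasm, and each was assigned by the name of its worksheet. The nuclear samples were not analysed here.

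Each deposited table held 1 row per called cluster, a stretch of crosslinked RNA with its position, strand, sequence, annotation class and gene symbol. The read, distinct-sequence and conversion columns held raw counts per cluster, as deposited by the authors with no normalization in the file headers. The shares of converted reads and of reads ending in G were deposited as a fraction between 0 and 1. Reads were demultiplexed with bcl2fastq 2.17.1 and the genome build was mm10, per the submitters' processing notes. The aligner, the cluster caller and its settings, and whether libraries were pooled before calling are not given in the sources used here. Coordinates are 1-based on mm10, as the tables give them, and cluster sequences matched their coordinates in length. Before use, 4 lines of the ESC table and 1 line of the myotube table were found blank. The unconverted, converted and otherwise mismatched reads added up to the cluster's read count exactly in 99.5% of ESC clusters and 99.4% of myotube clusters. Of 1707 gene symbols in the tables, 1638 (96.0%) matched a mouse Ensembl gene name. Every cluster in both tables had at least 2 conversion positions, and the smallest clusters had 4 reads in ESCs and 5 in myotubes. A gene without a cluster was therefore below a calling limit rather than at 0. No bound on a ratio was given for such genes, although the fixed design had foreseen one.

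With 1 library per group, no test between the cell types was made and no p-value was given for a difference between them. The cell type, the source of Argonaute and the capture method changed together between the libraries. Shares were given with exact Clopper-Pearson 95% intervals. The share of a library's cluster reads per gene was compared as a log2 ratio with an exact conditional binomial 95% interval. Intervals covered counting error only, since PCR reads without molecular identifiers are not independent molecules. Clusters were called shared when they overlapped by at least 1 nt on the same strand (bedtools 2.31.1). For each of 14 gene lists, the members with a cluster were counted. The number with a myotube cluster was placed among 10000 random gene lists of as many genes as the list had members with a cluster in either table, drawn from all genes with a cluster in either table and matched on mean read share in 5 bins. The lists covered pluripotency, muscle, cell cycle, the miRNA pathway, chromatin, TGF-beta and Nodal signalling, extracellular matrix, ribosomal proteins, literature targets of let-7, of miR-1 and miR-133, and of the miR-290 family, and markers of neurons, of blood and liver, and of fibroblasts. A percentile was given for lists with at least 5 members in the tables.

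Seed matches were sites of 7 nt complementary to miRNA bases 2 to 8 (7mer-m8), for 39 miRNA families of which 5 belong to other tissues. Sites were searched within the cluster sequences only, because no genome sequence was at hand to look beyond the cluster ends. A family is called here by its first member, so that the miR-17 family includes miR-20, the miR-290 family includes miR-302, the miR-15 family includes miR-16, and the miR-1 family includes miR-206. The number of clusters with a site was set against 1000 shuffles of each cluster sequence that kept its dinucleotides. The test was a one-sided permutation test within a library, with Benjamini-Hochberg adjustment over the 39 families. The smallest p it can give is 0.001. It compares sequences of 1 library with their own composition, and clusters are not replicates of a condition. The distance from the cluster's mode position to the first base of a site was compared with the same shuffles, and 3'UTR and coding clusters were compared with Fisher's exact test within a library. Simulated data were used to check the methods. With 3 families planted in 27 or 53 of the 2659 ESC clusters, or in 9 or 18 of the 889 myotube clusters, all 3 were recovered each time. A family whose site overlaps a planted site was also called in 3 of the 4 simulations. The ratio interval covered the simulated value in 96.0%, 95.7% and 95.3% of 2000 genes at log2 ratios of 0, 1 and 3. The simulated reads were independent of each other, so this checks the calculation only. It does not show that the intervals hold for duplicated reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.

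The groups, lists, families, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 8 genes with the most reads in mRNA clusters of each table. Of genes in both tables with at least 20 reads, it named the 6 with the largest and the 6 with the smallest read-share ratio whose interval excluded 0. It further named up to 4 genes with the most reads per list, the 5 overlapping cluster pairs, among those with a gene symbol, whose smaller read count was largest, and the 3 mRNA clusters with the most reads for each of the 3 most enriched seed families of a table. A gene that this rule names is not reported here. Alternatives were clusters with at least 10 reads, weighting by reads, other overlap limits, other denominators, 3'UTR clusters only, sites of 6 or 8 nt, single-base shuffles, the 665 ESC and corresponding myotube clusters with the most reads, clusters with at least 5 conversion events, and an ESC table reduced to the number of myotube clusters. The criterion of the test on tRNA copies was changed after its values were seen, from the share of clusters with the motif to their converted share and then to both together. Chosen after seeing the data were distinct sequences in place of reads, tables without mitochondrial or noncoding clusters, a denominator of mRNA reads outside the mitochondria, and ESC clusters without a miR-17 or miR-290 site.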

Results

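Argonaute (AGO) proteins carry miRNAs to their target RNAs, and the series set out to find the RNAs that AGO binds in embryonic stem cells and, as a second cell type, in C2C12 myotubes, the muscle fibres formed by a mouse myoblast line. Cluster tables of 1 cytoplasmic library per cell type were analysed. The ESC table held 2659 clusters with 214955 reads, and the myotube table held 889 clusters with 135023 reads. Clusters had a median of 9 reads in ESCs and 11 reads in myotubes, and a median length of 22 nt and 24 nt. ESCs expressed tagged AGO2 that was captured through its FLAG tag, whereas endogenous AGO was captured from myotubes. All differences below were between these 2 libraries, without a replicate check, and the intervals covered counting error only. RNA levels were not measured here, so a difference in AGO binding cannot be told apart from a difference in the level of the RNA.

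Messenger RNA made up most clusters in both cell types, with the 3'UTR, where miRNA sites usually lie, as the largest class. In ESCs, 1325 clusters (49.8%, 95% interval 47.9 to 51.7) lay in the 3'UTRs of 871 genes. In myotubes, 40.8% of clusters (interval 37.6 to 44.1) lay in the 3'UTRs of 275 genes. Coding sequence of nuclear genes held 21.0% of ESC clusters (interval 19.5 to 22.6) and 8.55% of myotube clusters (interval 6.79 to 10.6). The mitochondrial chromosome held 3.72% of ESC clusters (interval 3.04 to 4.51) and 13.6% of myotube clusters. Reads were distributed differently from clusters. Mitochondrial transcripts took 27.6% of ESC reads and 50.3% of myotube reads, while 3'UTR clusters took 7.25% and 2.92%. Among clusters with at least 10 reads, the 3'UTR share was 43.8% in ESCs and 24.9% in myotubes.

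**Figure D1:**
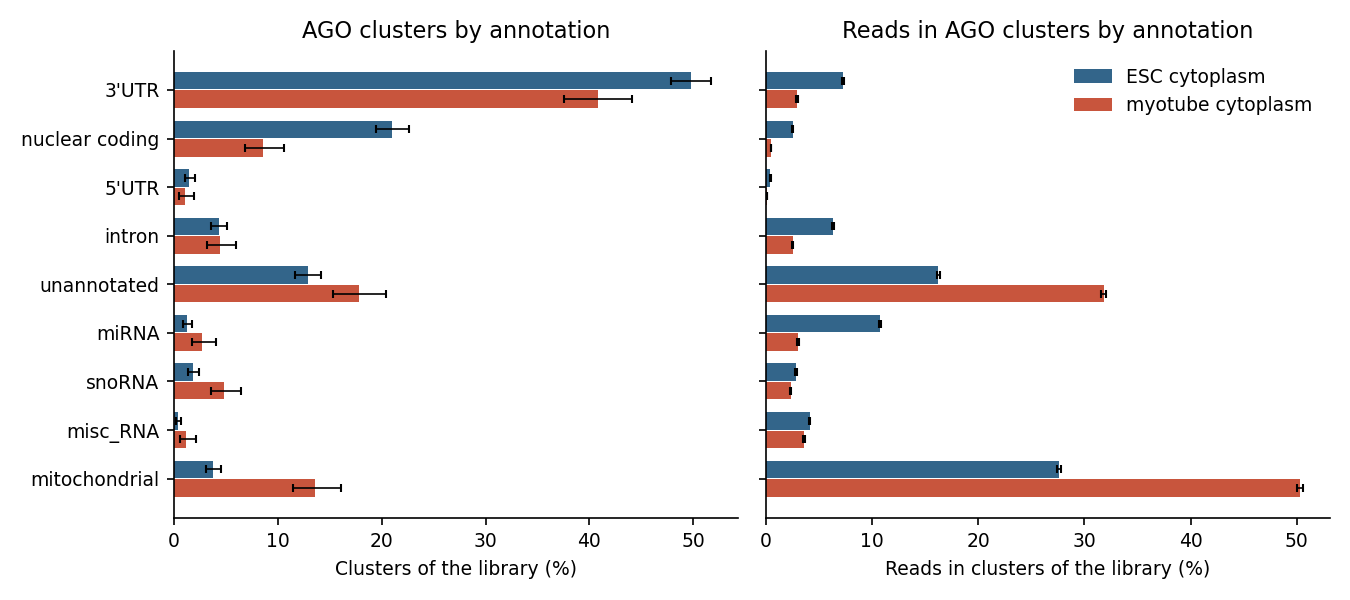
Share of clusters (left, %) and of reads in clusters (right, %) per annotation class in the ESC library (blue) and the myotube library (red), with exact 95% intervals as error bars. The 3'UTR held 49.8% of ESC clusters and 40.8% of myotube clusters, whereas the mitochondrial chromosome held 27.6% and 50.3% of the reads.

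Clusters at miRNA genes differed between the cell types. The loci given here were chosen after their values were seen, except Mir135b. In ESCs, 43654 reads (20.3% of the library) fell on a cluster at chromosome 11, 87756903 to 87756925, annotated to an intron of the noncoding gene A430104N18Rik, whose sequence TGTAGTGTTTCCTACTTTATGGA is that of mature miR-142-3p. Another 20403 ESC reads (9.49%) fell on Mir135b at chromosome 1, 132198101 to 132198125. In myotubes Mir135b had 87 reads, and no cluster with the miR-142-3p sequence was called. The leading miRNA cluster in myotubes lay in Mir322 (chromosome X, 53054306 to 53054327) with 1776 reads, followed by Mir335 with 914 reads and Mirlet7g with 531 reads. Mir206, a miRNA gene of skeletal muscle, had 184 reads in myotubes, at chromosome 1, 20679017 to 20679040. A cluster with 16 reads lay in Mir133a-2. The Mir206 sequence lacked the complement of the miR-1 site, and the Mir133a-2 sequence that of the miR-133 site. These reads therefore do not show the miRNAs whose sites are searched below. No ESC cluster was annotated to Mir206, Mir133a-2 or Mir322. Other loci followed the seed matches given below only in part. ESC clusters at Mir25, Mir92-2 and Mir32 held the complement of the miR-25 site, and these genes had no myotube cluster. Mir27b had 891 reads in ESCs and no myotube cluster. No ESC cluster was annotated to a gene of the miR-290 or miR-17 family. Mir20a of the miR-17 family had 14 reads in myotubes and no ESC cluster. The Mir20a sequence lacked the complement of the miR-17 site, so its reads do not show a miRNA that pairs with that site.

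To find the binding sites common to both cell types, clusters were intersected by position. Overlap was frequent on mitochondrial RNAs and snoRNAs. In all, 309 ESC clusters (11.6%, interval 10.4 to 12.9) overlapped 306 myotube clusters (34.4%, interval 31.3 to 37.6). Of the mitochondrial clusters, 87 of 99 in ESCs and 84 of 121 in myotubes were shared. For snoRNAs, which guide RNA modification, 26 of 49 ESC clusters and 26 of 43 myotube clusters were shared. At miRNA genes, 5 of 33 ESC clusters (15.2%) and 5 of 24 myotube clusters (20.8%) were shared. In 3'UTRs, 80 of 1325 ESC clusters (6.04%, interval 4.82 to 7.46) and 80 myotube clusters (22.0%, interval 17.9 to 26.7) were shared. Among pairs with a gene symbol, the leading pair lay in the mitochondrial alanine tRNA gene mt-Ta, with 8918 ESC and 10703 myotube reads. It was followed by the ribosomal RNA mt-Rnr1 (4686 and 3699 reads) and the Y RNA Rny1 on chromosome 6 (5048 and 2261 reads). Pairs in mt-Nd4 (1765 and 1933 reads) and mt-Nd1 (2439 and 1732 reads) came next. By gene, 1461 genes had a cluster in ESCs and 483 in myotubes, and 237 genes were common to both. A further 1224 genes had a cluster in the ESC table alone and 246 in the myotube table alone. With at least 10 reads per cluster 108 genes were common, and with 3'UTR clusters only 117 genes.

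Mitochondrial mRNAs of the respiratory chain carried the most mRNA reads in both libraries. The 6 leading genes were the same in ESCs and myotubes, namely mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Co1. mt-Cytb had 9577 reads in ESCs and 11731 in myotubes, and mt-Nd1 had 8156 and 12677. The leading nuclear mRNAs differed. In ESCs they were Nucks1, a chromatin-associated protein, with 290 reads in 16 clusters at chromosome 1, 131931100 to 131936017, and the metallothionein Mt2 with 282 reads in 1 cluster of its 3'UTR at chromosome 8, 94173500 to 94173528. Of the Nucks1 clusters 15 lay in the 3'UTR, and Nucks1 had no cluster in myotubes. In myotubes they were Tmsb4x, which encodes the actin-sequestering thymosin beta 4, with 189 reads in 3 clusters of its 3'UTR on chromosome X, and the sialomucin gene Cd164, with 112 reads in 9 clusters on chromosome 10. In ESCs Tmsb4x had 41 reads and Cd164 had 39 reads.

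The read shares of the 237 common genes were then compared between the libraries. At the low end stood 3 genes of the muscle fibre. Tpm2, a tropomyosin, had a log2 ratio of ESC over myotube read share of -3.90 (interval -5.59 to -2.58), the regulatory myosin light chain Mylpf -3.87 (interval -4.86 to -3.00) and the giant sarcomere protein titin, Ttn, -3.26. Igfbp5, an insulin-like growth factor binding protein, was lowest at -4.20 (interval -5.56 to -3.10), with 8 clusters in myotubes and 1 cluster of 24 nt in ESCs. The microtubule-associated Map1b stood at -3.63 and the stress-response transcription factor Atf4 at -3.22. At the high end, Mir135b stood at 7.20 (interval 6.90 to 7.52), the fibronectin gene Fn1 at 3.97 (interval 2.82 to 5.44) and Ssr3, a subunit of the translocon-associated complex, at 3.33 (interval 2.05 to 4.99). The snoRNA genes Snord13 and Gm22680 stood at 3.74 and 3.43. Counted by distinct sequences instead of reads, a choice made after seeing the data, Mir135b stood at 2.31 (interval 1.30 to 3.50), Snord13 at 1.71, Gm22680 at 1.59 and Atf4 at -1.73. The myogenic factor Mef2a stood at 3.88, but 531 of its 539 ESC reads lay in 1 intronic cluster. With 3'UTR clusters only its ratio reversed to -2.19, and that of Mylpf moved to -0.89 with an interval that included 0. These sums depended on how much of a gene was called, and the values per nt given here are raw reads that were not divided by the library totals. Fn1 had 1.11 reads per nt over 135 nt in ESCs and 0.286 over 21 nt in myotubes, Ssr3 0.708 over 113 nt and 0.250 over 20 nt, and Mylpf 0.600 over 20 nt and 2.62 over 42 nt. Igfbp5 had 0.292 reads per nt in ESCs and 0.393 in myotubes, Ttn 0.300 over 20 nt and 0.486 over 74 nt, and Tpm2 0.238 over 21 nt and 0.5 over 94 nt. Map1b had 0.238 over 21 nt and 0.696 over 56 nt, and Atf4 0.280 over 25 nt and 0.891 over 46 nt. The clusters of Igfbp5, Ttn, Tpm2, Map1b, Ssr3 and Mef2a lay at different positions in the libraries.

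Over all common genes the interval lay above 0 for 60 genes and below 0 for 62, and it included 0 for 115. The median log2 ratio was -0.04. This balance depended on the denominator. With mRNA reads as the total, 89 genes were higher and 45 lower in ESCs, with the median moved by 0.48. With the reads of common genes, 78 were higher and 51 lower, with the median moved by 0.30. With mRNA reads outside the mitochondria, a denominator chosen after seeing the data, 13 were higher and 139 lower, and the median moved by -1.54. A change of the total moves all genes alike.

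**Figure D2:**
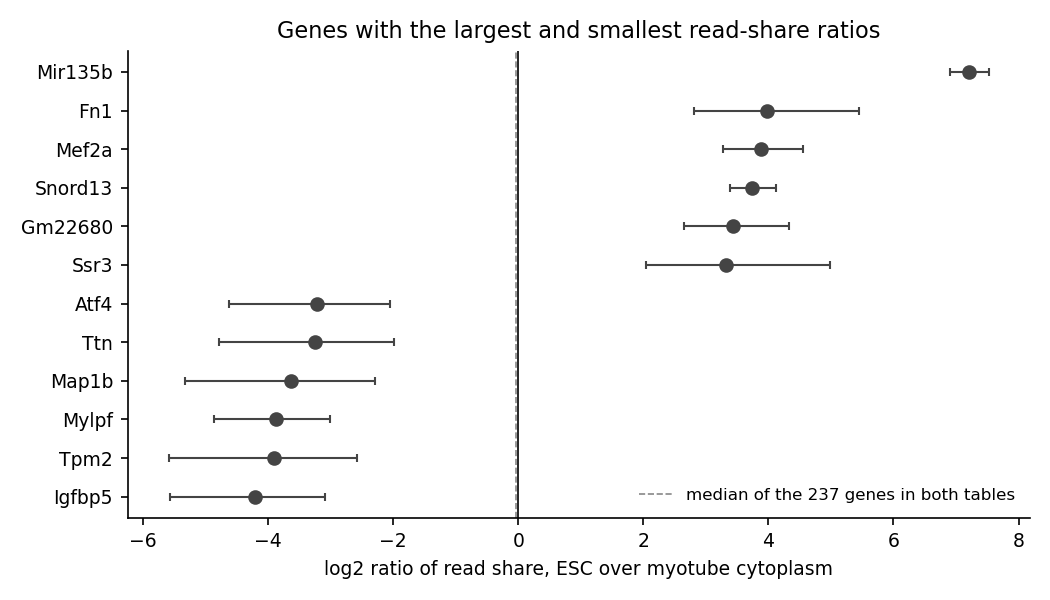
Log2 ratio of read share, ESC over myotube cytoplasm (x axis), for the 12 genes with the largest and smallest ratios (y axis), with exact 95% intervals for counting error. Values ran from -4.20 for Igfbp5 to 7.20 for Mir135b, and the dashed line marks the median of -0.04 over 237 genes.

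Genes of the pluripotency network were bound in ESCs and had no cluster in myotubes. Of 36 pluripotency genes, 14 had ESC clusters and 0 had a myotube cluster, against a mean of 6.27 in random lists of 14 matched genes with a cluster, of which 0.02% held so few. Over all 1707 gene symbols with a cluster, 483 had one in myotubes, a lower share than in these matched lists. The gap to the matched mean is therefore wider than the gap to that share. Tfcp2l1, a transcription factor of naive pluripotency, had 198 reads in 16 clusters at chromosome 1, 118632372 to 118685055, of which 15 lay in the 3'UTR. Sox2 had 137 reads in 5 clusters, of which 3 lay in the 3'UTR, at chromosome 3, 34650162 to 34652293. Nanog had 117 reads in 3 clusters at chromosome 6, 122707681 to 122714196. Klf2 had 79 reads in 1 cluster of its 3'UTR. Muscle genes showed the opposite distribution, with 13 of 47 genes bound in myotubes and 5 in ESCs. The mean of random lists of 14 genes with a cluster was 6.52, and 99.96% of random lists had fewer than 13. Beside Mylpf, Tpm2 and Mef2a, the genes bound in myotubes included the myogenic regulator Myog (49 reads), the acetylcholine receptor subunit Chrna1 (46 reads) and the cardiac actin gene Actc1 (44 reads), named after their values were seen. The satellite cell factor gene Pax7 had a cluster in the ESC table only, an intronic one with 448 reads that held a tRNA promoter-box motif. Without intronic and noncoding clusters, 12 muscle genes were bound in myotubes and 4 in ESCs. Neither list separates AGO binding from the expression of its genes in the cell type, which was not measured here.

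Of 35 genes for chromatin regulators, 14 had ESC clusters and 2 had myotube clusters. The random mean in myotubes was 4.07, and 14.7% of random lists had 2 or fewer, or 81.7% with at least 10 reads per cluster, so the list did not stand apart from random lists. The DNA demethylase gene Tet1 had 125 reads in 13 ESC clusters at chromosome 10, 62804959 to 62838737, and the DNA methyltransferase gene Dnmt1 had 34 reads in ESCs. Both genes lacked a myotube cluster. The heterochromatin protein gene Cbx5 had 105 reads in 12 ESC clusters and 26 reads in 3 myotube clusters, all in the 3'UTR. The remodeller gene Chd4 had 51 and 22 reads. Of 32 cell cycle genes 10 had a cluster, with 5 bound in each library and 0 in both. Over all 1707 gene symbols with a cluster 237 were in both, so a list of this size cannot show that its genes were divided. The myotube set included the cell cycle inhibitor genes Cdkn1c (19 reads) and Rb1 (12 reads) and the cyclin gene Ccnd3 (10 reads), and the ESC set included the cyclin gene Ccna2 (12 reads). Growth-restraining genes were also in the ESC set, namely Cdkn1b (10 reads), Rbl1 (8 reads) and Btg2 (7 reads), which were chosen after their values were seen. Of random lists, 91.7% had fewer than 5 genes bound in myotubes, and with at least 10 reads per cluster 98.6% had fewer than the 3 genes that remained.

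Of 22 miRNA pathway genes, 6 were bound in ESCs and 4 in myotubes, with 3 in both. They were led by the deadenylase subunit gene Cnot6l (44 ESC and 65 myotube reads) and the helicase gene Ddx6 (35 and 13 reads), followed by Cnot7 (9 and 6 reads). Ago2 itself had 8 reads in 1 cluster of its 3'UTR in ESCs. Of 22 TGF-beta and Nodal genes, 6 were bound in ESCs and 3 in myotubes. The inhibitory Smad7 was bound in both with 25 and 7 reads, the receptor gene Tgfbr1 in myotubes with 15 reads, and the repressor genes Ski (13 reads) and Skil (11 reads) in ESCs. Of 27 extracellular matrix genes, 5 were bound in each library. Thbs1 (33 reads) was bound in myotubes, Sparc (18 reads) in ESCs, and Fn1 and Fstl1 (5 ESC and 15 myotube reads) in both. The 4 ribosomal protein genes with a cluster had one in ESCs, namely Rpl3, Rpl8, Rpl15 and Rplp0, and Rpl3 had an intronic cluster in both (481 and 247 reads). With mRNA clusters only Rpl3 dropped out, which left 3 of these genes in ESCs and 0 in myotubes. The Rpl3 cluster held the sequence ATGATGA, which was found in 13 ESC and 10 myotube clusters, none of them on mRNA. It is therefore not evidence of binding to the ribosomal protein mRNA.

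Of 22 literature targets of let-7, 2 were bound in myotubes. Trim71 (46 reads) and Igf2bp1 (36 reads) had 4 clusters each in ESCs, and Col3a1 had 11 reads in myotubes. The clusters of Igf2bp1 and Col3a1 did not hold the let-7 site. Literature targets of miR-1 and miR-133 were bound in 11 of 23 cases in ESCs and 5 in myotubes. The members with the most reads were Mef2a, Pax7, Tmsb4x and Fn1, but Mef2a and Pax7 led through intronic ESC clusters. With mRNA clusters only, Mef2a had 8 ESC and 23 myotube reads and Pax7 had no cluster. The clusters of Mef2a, Pax7 and Fn1 held neither the miR-1 nor the miR-133 site. Literature targets of the miR-290 family were bound in 5 of 16 cases in ESCs and 1 in myotubes. Ei24 had 119 reads in 7 ESC clusters, Ereg had 177 reads in an intron, and Arid4b had 6 reads. The cell cycle inhibitor gene Cdkn1a had 10 reads in myotubes. None of the clusters of Ei24, Ereg, Arid4b and Cdkn1a held the miR-290 site, so their binding cannot be credited to that family from these sequences. Sequence beyond the cluster ends was not searched for any family, so a site next to a cluster is not excluded. The share of random lists with fewer genes bound in myotubes was 30.9%, 37.5% and 10.8% for these target lists, 89.5% for the miRNA pathway, 70.1% for TGF-beta and Nodal genes and 91.4% for the extracellular matrix. These shares changed with the choice of clusters. For the miR-1 and miR-133 targets the share was 3.46% with at least 10 reads and 65.8% with mRNA clusters only, and for the miR-290 family targets it was 32.6% with mRNA clusters only. Markers of other cell types were nearly absent. Of 10 neuronal markers Stmn2 had 6 reads in ESCs, and 0 of 10 blood and liver markers and 0 of 10 fibroblast markers had a cluster in either library.

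**Figure D3:**
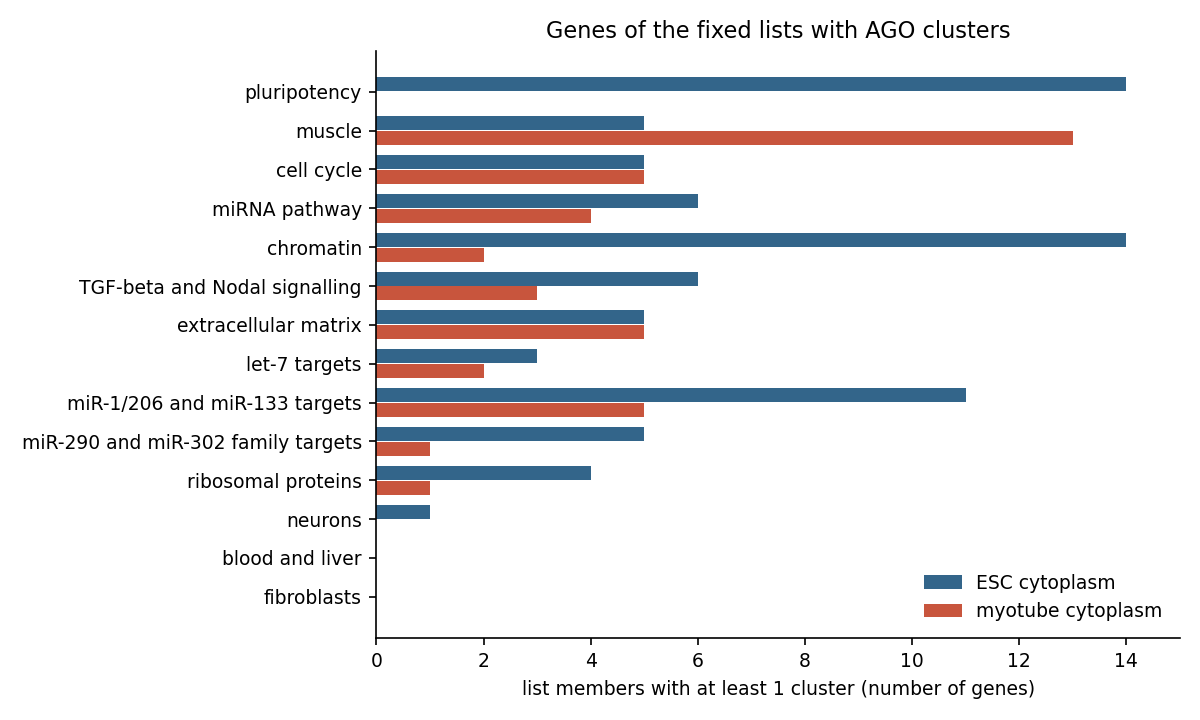
Number of genes with at least 1 AGO cluster (x axis) per fixed gene list (y axis) in the ESC library (blue) and the myotube library (red). The pluripotency list had 14 genes in ESCs and 0 in myotubes, and the muscle list had 5 and 13.

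Cluster sequences were then searched for miRNA seed matches. In ESCs the sites of the miR-17 family and of the ESC-specific miR-290 family led. A miR-17 site (GCACTTT) was found in 56 clusters (2.11%, interval 1.59 to 2.73), 13.6 times the mean of the shuffled sequences, with an adjusted permutation p of 0.00649. A miR-290 site (AGCACTT) was found in 39 clusters (1.47%, interval 1.05 to 2.00), 12.7 times the shuffled mean, with the same adjusted p. These sites overlap in sequence, and 20 clusters held both. In myotubes the miR-17 site was found in 2 clusters (0.225%, interval 0.0273 to 0.810) and the miR-290 site in 3 (0.337%, interval 0.0696 to 0.983), and neither passed (adjusted permutation p of 0.633 and 0.302). Sites of miR-25 (6 clusters, 8.21 times), miR-15 (13 clusters, 7.32 times), miR-130 (28 clusters, 6.19 times) and miR-19 (13 clusters, 3.24 times) shared the adjusted p of 0.00649, which stands for the smallest p that the permutations could give. Of the miR-19 clusters 10 also held a miR-130 site. Sites of miR-27 (4 clusters, 6.07 times, adjusted permutation p 0.0111), miR-124 (5 clusters, 5.76 times, 0.0146) and let-7 (20 clusters, 1.78 times, 0.0476) completed the 9 families called in ESCs. miR-124 was in the set as a family of the nervous system, and its call was lost under 5 of 9 alternatives and that of let-7 under all 9. The calls of miR-27, miR-19 and miR-25 were kept under 5, 6 and 7 of 9 alternatives, and those of miR-15 and miR-130 under 8. The let-7 site was not particular to ESCs. In myotubes it was found in 9 clusters (1.01%), 2.37 times the shuffled mean, and did not pass (adjusted permutation p 0.0935).

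In myotubes 3 of the 39 families passed, among them the muscle miRNA miR-133. Its site (GGACCAA) was found in 8 clusters (0.900%, interval 0.389 to 1.77), 19.3 times the shuffled mean, with an adjusted permutation p of 0.0130. It was found in 1 ESC cluster (0.0376%, interval 0.000952 to 0.209). The miR-27 site was found in 8 myotube clusters, 14.9 times the shuffled mean, and the miR-15 site in 9, 6.08 times, both with an adjusted p of 0.0130, which again stands for the smallest permutation p. The site of miR-1, the other muscle family, was found in 9 clusters, 2.28 times the shuffled mean, and did not pass (adjusted permutation p 0.169). Its shuffled mean was 3.95 clusters, against 0.415 for the miR-133 site, so a similar number of clusters gave a lower ratio. The 2 results therefore do not show that miR-1 sites were rarer than miR-133 sites. Each of the 3 myotube families passed under 6 of 7 alternatives. The exception was the upper quartile of myotube clusters by reads, in which 0 families passed and the miR-133 site was found 13.4 times as often as in shuffled sequences (adjusted permutation p 0.156, with a range over the alternatives from 0.00557). With the ESC table reduced to 889 clusters, 5 families passed in ESCs, and the miR-17 site was found in 25 clusters and the miR-133 site in 0.

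**Figure D4:**
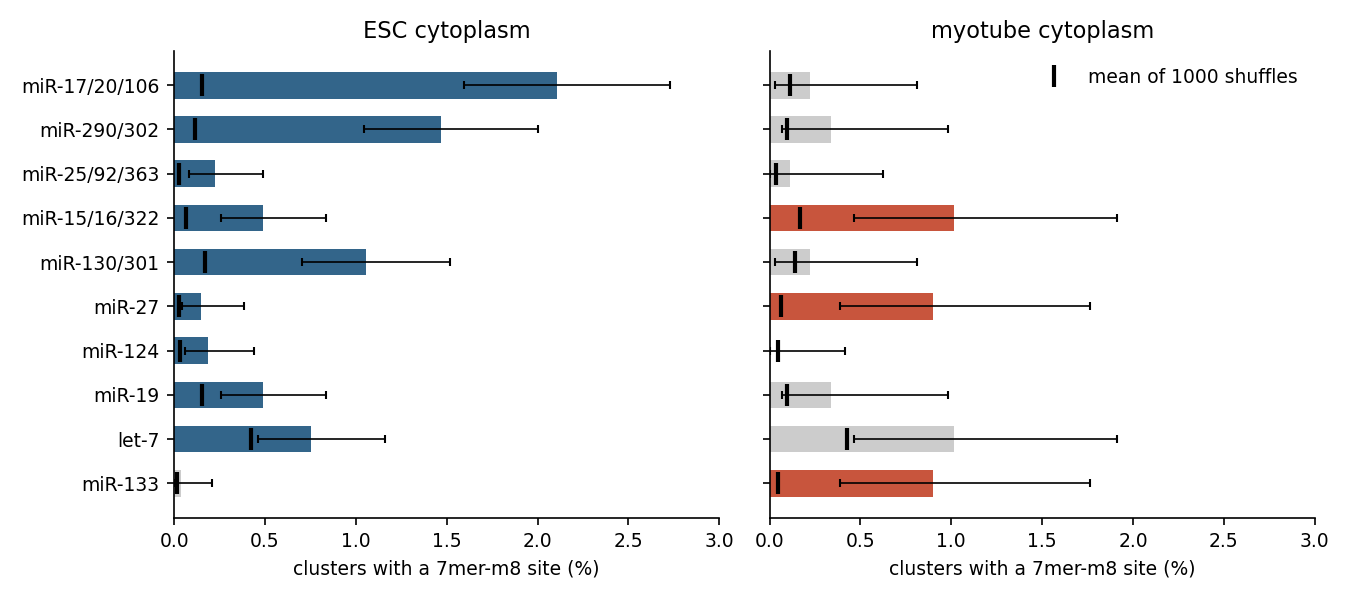
Share of clusters with a 7mer-m8 site (x axis, %) for the miRNA families called in either library (labels give their members) (y axis), with exact 95% intervals; coloured bars passed an adjusted p of 0.05 in that library, grey bars did not, and black ticks mark the mean of 1000 shuffles. The miR-17 site reached 2.11% of ESC clusters and 0.225% of myotube clusters, and the miR-133 site 0.0376% and 0.900%.

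Most clusters with a site of the leading families lay in mRNA, with 53 of 56 for miR-17 and 33 of 39 for miR-290 in ESCs. In myotubes 6 of 8 did for miR-133, 7 of 8 for miR-27 and 5 of 9 for miR-15. Clusters at miRNA genes were counted as well. The miR-15 clusters of both libraries included a Mir16-2 cluster, the myotube miR-290 clusters included Mir20a, and the ESC miR-130 clusters included Mir25 and Mir92-2. In ESCs, miR-17 sites with the most reads lay in the 3'UTR of Pafah1b2 (chromosome 9, 45968605 to 45968626, AATCCTTTCTTAAGGCACTTTG, 113 reads), in coding sequence of Npepps (chromosome 11, 97213770 to 97213790, TCCTTACTTTTGCACTTTCAG) and in the 3'UTR of the corepressor gene Tle4 (chromosome 19, 14449688 to 14449710, ACTCCTCCTCATAGCACTTTGCG, 92 reads). The Tle4 cluster also held the miR-290 site, as did 3'UTR clusters of Kdelr2 (chromosome 5, 143421745 to 143421764, 84 reads) and Ssr1 (chromosome 13, 37978664 to 37978691, 37 reads). The Klf2 cluster (chromosome 8, 72321122 to 72321144, TTTTCAAAATGGTGCAATAATTG) held a miR-25 site, as did 3'UTR clusters of Tob1 (40 reads) and Usp28 (39 reads). In myotubes, miR-133 sites lay in the 3'UTRs of the phosphatase subunit gene Ppp2cb (chromosome 8, 33619319 to 33619346, ACATTAAAACACATCATGGACCAAAACG, 77 reads), the clathrin light chain gene Clta (chromosome 4, 44032659 to 44032680, 14 reads) and the actinin gene Actn4 (chromosome 7, 28893689 to 28893714, 12 reads). miR-27 sites lay in the 3'UTRs of Tnpo1 (chromosome 13, 98843011 to 98843032, ATTTTCTTACATACTGTGAATG, 41 reads), Tmbim6 (28 reads) and Wisp1 (14 reads), and miR-15 sites in those of Zfhx4 (18 reads), Rbms1 (9 reads) and Rreb1 (8 reads). Of these sites, 3 lay in clusters shared by both libraries. The Tnpo1 site was also bound in ESCs with 7 reads, the miR-133 site in Clta was bound in ESCs with 8 reads, and the miR-25 site in Tob1 was bound in myotubes with 9 reads.

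Seed sites were not more frequent in 3'UTR clusters than in coding clusters by the test used. Of ESC clusters, 130 of 1325 in 3'UTRs (9.81%, interval 8.26 to 11.5) and 53 of 614 in coding sequence (8.63%, interval 6.53 to 11.1) held a site of any of the 39 families, with a two-sided Fisher exact p of 0.453. In myotubes 43 clusters in 3'UTRs (11.8%, interval 8.71 to 15.6) and 10 in coding sequence (6.58%, interval 3.20 to 11.8) did, with p of 0.0810. Coding sequence here included mitochondrial mRNAs. Without the mitochondrial chromosome, 7 of 76 coding clusters in myotubes (9.21%) held a site, with a two-sided Fisher exact p of 0.691. In ESCs 51 of 558 (9.14%) did, with a two-sided Fisher exact p of 0.732. The first base of a site lay a median of 1 nt downstream of the mode position in both libraries. In ESCs the median of the shuffled sequences was -2 nt, with a two-sided permutation p of 0.0410 over 284 sites. For the called families alone the ESC median was also 1 nt, with a two-sided permutation p of 0.275 over 185 sites. In myotubes the median of the shuffled sequences was -3 nt over all families, with a two-sided permutation p of 0.125 over 91 sites.

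Conversions marked most reads of a typical cluster. The median share of converted reads was 80% of a cluster's reads in ESCs (quartiles 58.5% and 100%) and 83.3% in myotubes (quartiles 60.8% and 100%). 3'UTR clusters had medians of 77.8% and 90%, mitochondrial clusters 49.5% and 59.6%, and miRNA clusters 40% and 50%. Intronic clusters had a median of 100% in both libraries. Among clusters with at least 10 reads the overall medians were 64.3% and 67.1%. The libraries differed more when all cluster reads were pooled, with 50.7% converted in ESCs and 69.0% in myotubes. In clusters with at least 10 reads the pooled shares were 49.2% and 68.6%.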

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

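The tests in this part on miR-142-3p, blood cells, mitochondrial RNA and tRNA copies were chosen after the result was seen, the wording for a variant base was changed after its result was seen, and the test on few reads per cluster was set before. Reads with a mismatch other than T-to-C entered no comparison and stood above the limit that a count of 0 allows. They made up 3.02% of ESC cluster reads (6502 reads) and 3.47% of myotube cluster reads (4688 reads).

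The miR-142-3p cluster held 20.3% of ESC reads in 80 distinct sequences, and miR-142-3p is best known from blood cells. If the reads came from a library product that was not bound to AGO2, its targets should not be enriched. The miR-142-3p site was found 1.42 times as often as in shuffled sequences over all ESC clusters (adjusted permutation p 0.340), and 2.41 times as often in 3'UTR clusters (adjusted permutation p 0.0292, with a range over the alternatives up to 0.849), so the result differed with the choice of clusters. Blood cells among the ESCs could be another source, but 0 of 10 blood and liver markers had a cluster, and a gene missing from a table of called clusters excludes nothing. Both explanations, and expression in the ESCs themselves, remain open.

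Mitochondrial RNA held 27.6% of ESC reads and 50.3% of myotube reads. A candidate explanation is recovery of mitochondrial RNA without miRNA pairing. In ESCs 1 of 99 mitochondrial clusters held a site of a called family, against 6.42% of 3'UTR clusters (two-sided Fisher exact p 0.0261). In myotubes 1 of 121 did, against 4.13% (two-sided Fisher exact p 0.137), and 0 families passed among the mitochondrial clusters of either library. These families were called over all clusters, most of them outside the mitochondria, so the comparison favours 3'UTRs in advance and decides nothing, and the explanation stays open.

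Intronic and unannotated clusters outside the mitochondria had a median of 98.6% converted reads in ESCs and 95.2% in myotubes, against 77.8% and 90% in 3'UTRs. tRNA fragments aligned to other copies in the genome could leave such mismatches. A tRNA promoter-box motif was present in 16.2% of these clusters in ESCs and 35.0% in myotubes, against 0.679% and 0.275% of 3'UTR clusters, but clusters with the motif had lower medians (82.2% and 90%) than those without it (100% and 100%), so the motif share goes with this explanation and the conversion values do not, and which of them was to decide was changed after both were seen. Few reads per cluster are argued against, since with at least 10 reads the medians exceeded those of 3'UTRs by 25.8 points in ESCs and 17.3 points in myotubes (two-sided permutation p of 1e-05, the smallest possible, and 6e-05). A variant base read as conversion could not be tested, because the tables list only clusters with at least 2 conversion positions (0% with 1 position), so this and tRNA copies, including fragments without the motif, stay open.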

How the results depend on the processing

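Choices of clusters changed numbers more often than directions. Alternatives without the mitochondrial chromosome, with mRNA reads outside it, with distinct sequences, with mRNA clusters only and without clusters with a miR-17 or miR-290 site were chosen after seeing the data. With at least 10 reads per cluster, the 3'UTR share was 43.8% in ESCs and 24.9% in myotubes, the nuclear coding share 15.7% and 4.78%, and the mitochondrial share 7.91% and 23.5%. Weighted by reads these shares were 7.25% and 2.92%, 2.54% and 0.487%, and 27.6% and 50.3%. Without the mitochondrial chromosome the 3'UTR share was 51.8% and 47.3%. The numbers of overlapping clusters stayed within 1.5 times (294 with a stricter overlap and 341 within 50 nt in ESCs). Common genes fell to 108 with at least 10 reads and to 117 in 3'UTRs, because fewer genes remained. Genes higher and lower in ESCs numbered 28 and 21 in 3'UTRs, 13 and 139 with mRNA reads outside the mitochondria, and 45 and 31 with distinct sequences. Other totals move all named ratios alike, so only 3'UTR clusters and distinct sequences could change single genes. Mef2a reversed to -2.19 in 3'UTRs because its intronic cluster was left out, and its interval included 0 with distinct sequences (0.15), as did that of Mylpf in 3'UTRs (-0.89).

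List members fell with the number of clusters. With at least 10 reads, ESC and myotube counts were 3 and 8 for muscle, 2 and 3 for cell cycle, 2 and 1 for the miRNA pathway, 2 and 1 for TGF-beta and Nodal genes, 3 and 3 for extracellular matrix, 7 and 2 for miR-1 and miR-133 targets, and 2 and 0 for miR-290 family targets. ESC counts were 8 for chromatin and 0 for neurons, and the myotube count was 1 for let-7 targets. In 3'UTRs, ESC counts were 3 for muscle, 2 for cell cycle, 8 for chromatin, 3 for extracellular matrix, 3 for miR-290 family targets, 2 for ribosomal proteins and 0 for neurons. Myotube counts were 1 for let-7 targets and 0 for ribosomal proteins, the latter also with mRNA clusters only (0). Pluripotency counts stayed between 11 and 14 in ESCs and at 0 in myotubes.

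Seed families called in ESCs numbered 5 with sites of 8 nt, 3 in the upper quartile of clusters by reads and 5 with as many clusters as in myotubes. In myotubes they numbered 8 with sites of 6 nt, 5 in 3'UTRs and 0 in that upper quartile. Only the miR-17 and miR-290 sites in ESCs passed under every alternative run (8 each), at 1.51 to 19.4 and 10.2 to 20.1 times the shuffled mean. In the upper quartile, let-7 sites in ESCs reversed to 0.797 times and miR-27 sites in myotubes to 0 times; the cause was not tested. The Fisher tests and the conversion medians kept their side under all alternatives. With 4 or 5 reads in the smallest clusters, depth limits which sites could be called. No paired analysis was possible because each group has 1 library and no result comes from a test between groups.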

Other observations

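In this part, the items named were chosen after their values were seen, and the test on read depth was set before its result was seen. The sequence GCACTT of 6 nt lies in both the miR-290 and the miR-17 site. It was found in 115 ESC clusters (4.32%, interval 3.58 to 5.17), 11.6 times the mean of the shuffled sequences, and in 6 myotube clusters (0.675%, interval 0.248 to 1.46), 1.96 times. Of the ESC clusters, 75 held a miR-290 or miR-17 site of 7 nt already counted. In a search over all sequences of 7 nt in ESC clusters, TGCACTT (48 clusters, of which 41 lay in mRNA), GCACTTA (32 clusters) and GGCACTT (26 clusters) exceeded the highest of 1000 shuffles, although none of them was among the fixed sites. In myotubes GACCAAA, which overlaps the miR-133 site, was found in 9 clusters against a shuffled mean of 0.586. These were picked from 118 ESC and 88 myotube sequences that were in at least 5 clusters and exceeded all shuffles. Only 43 and 11 of them lay mostly in mRNA. The leading myotube sequences had 0 clusters on mRNA, among them TAGCTCA (43 clusters, 33.9 times the shuffled mean) and TGGTAGA (39 clusters, 45.8 times), against 15.4 times for GACCAAA.

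The fibronectin, tropomyosin and titin genes were not the only ones with clusters in both cell types. The splicing factor gene Qk had 7 clusters in each library, all in the 3'UTR, with 80 ESC reads and 56 myotube reads. The translational regulator gene Tob1 had 48 ESC reads and 18 myotube reads. Ccng1, a p53 target, had 177 reads in 10 clusters of its 3'UTR in ESCs and 30 reads in 3 clusters in myotubes. Slc2a3, a glucose transporter gene, had 213 reads in 8 ESC clusters, and Trp53inp1, another p53 target, had 155 reads in 11 ESC clusters. Polr2a, the largest subunit of RNA polymerase II, had 195 reads in 11 ESC clusters, of which 9 lay in coding sequence. None of Slc2a3, Trp53inp1 and Polr2a had a myotube cluster.

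Clusters on mRNA outside the mitochondria with a site of a called family had a median of 11 reads in ESCs (118 clusters), against 8 reads for clusters without one. The hypothesis that both kinds were equally deep was argued against in ESCs (two-sided permutation p 8e-05). In myotubes the medians were 8.5 reads (18 clusters) and 8 reads, with a two-sided permutation p of 0.787.

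The muscle gene Mylpf had a cluster at the same position in both libraries (chromosome 7, 127214255 to 127214274, 3'UTR) with 12 ESC reads and 14 myotube reads, while its cluster in the 5'UTR (127211706 to 127211727) had 96 reads in myotubes and no ESC cluster. The intronic ESC clusters of Pax7 (GCAGGTTCAAATCCTGCCCCTGCT, chromosome 4, 139806232 to 139806255) and Mef2a (GGAGAGGTGGCCGAGTGGTT, chromosome 7, 67339332 to 67339351) both held a tRNA promoter-box motif. The motif part TAGCTCA was found in 44 ESC clusters and 43 myotube clusters, none of them on mRNA. Reads ending in G made up 60.9% of ESC cluster reads and 46.7% of myotube cluster reads.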
